A study of Rattus norvegicus with 8 samples.

How the data were processed

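Gene expression was measured on 8 one-colour oligonucleotide microarrays (Agilent whole rat genome), each hybridised with Cy3-labelled cRNA from 1 culture of embryonic rat hippocampal cells. Per the labels, the hippocampi came from Wistar embryos of day 17 to 18, the cells were trypsin-dissociated and grown in Neurobasal medium with B-27, and the treatment began on day 12 in vitro. Nerve growth factor (NGF) was given at 100 ng/ml for 72 h to 4 cultures, and 4 cultures received vehicle for the same time. Labelling started from 1 μg of total RNA per culture, and 750 ng of cRNA was hybridised. The 4 cultures of each group were described as biological replicates from the same litter, so the p-values measure only the spread between these cultures and not that between litters.

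The deposited scanner tables held spot intensities, background-subtracted and detrended within each array by Agilent Feature Extraction 11.5.1.1 per the file headers and the submitters' processing notes. These intensity values were not normalized between arrays, and flags for saturation, outlier pixels and signal well above background stood beside them, per the file headers. The authors also deposited 1 table of log2 values for 30507 probes with no stated scale. Set against the scanner values, its columns were log2 processed signals on each array's 75th percentile minus the probe's median over the 8 arrays. On each array 97.7 to 98.3% of the probes lay within 0.01 of that construction, with slopes from 0.959 to 1.00, and the direction of the scale was that of the signal. Its column medians were −0.0011, −0.0163, 0.0087 and 0.331 for vehicle cultures 1 to 4 and 0.0329, 0.0190, −0.0443 and −0.111 for NGF cultures 1 to 4. A treatment note in the header of each of the 8 scanner tables named the same treatment as the label.

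Each array held 62976 spots, of which 58717 belonged to 30367 probes that were not controls. The files paired probes with transcript accessions and not with gene names. Names were therefore taken by matching the accession, without its version, to a RefSeq gene table of assembly GRCr8, where the rule fixed beforehand had counted on a name column. Of the probes, 18438 (60.7%) matched 1 of 15507 symbols and 11929 stayed unnamed. The array grid was annotated to another assembly (rn4, per the file headers), so no genome coordinates are given.

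The 75th percentile of the processed signal was 1760, 2160, 1260 and 422 on the arrays of vehicle cultures 1 to 4, and 1500, 1580, 1860 and 2730 on those of NGF cultures 1 to 4. Between 67.5% (vehicle 4) and 84.8% (vehicle 2) of the probes were well above background, 0 spots were saturated, and outlier flags covered 0.892 to 1.27% of the spots. The 8 arrays lay on 3 slides, each scanned on its own day. Slide 1 held vehicle 1 alone, slide 2 held vehicle 2 with NGF 1 and 2, and slide 3 held vehicle 3 and 4 with NGF 3 and 4.

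Processed signals were log2-transformed and each array's 75th percentile was subtracted, so that 0 marks a signal at that percentile. Outlier-flagged spots were then left out, spots of 1 probe were averaged and control spots were dropped. Probes well above background on at least 4 of the 8 arrays were kept, whatever the group, which left 24159 probes (79.6%), 19 of them with a missing value. Each gene was represented by the probe with the highest mean over the 8 arrays, which gave 12933 measured genes. No gene had probes past the threshold in opposite directions (0 genes). For a probe below that background on every array of a group, the fold set the brighter group's mean against a floored mean. That mean took, per array, the higher of the probe's own value and the lowest signal well above background. For Hbe2 the probe's own values were the higher, so its fold is the plain one and not a bound.

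NGF was compared with vehicle by limma (lmFit and eBayes, two-sided, no covariate) with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The study states a moderated test with the Westfall-Young correction. That step-down adjustment was run on the same statistic over the 35 distinct relabellings of 4 against 4 arrays, where the smallest adjusted p is 0.0286. Log2 changes are NGF minus vehicle. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 27 lists, each with at least 5 measured genes. Camera compares a list with all other measured genes. Counts of members that rose or fell use the adjustment over all probes, and counts "adjusted over the list alone" use only the list's members. The lists, in which a gene could recur, held 738 members, 685 of them on the array. They covered neurotrophins and their receptors, immediate early genes, cholinergic, pan-neuronal, glutamatergic and GABAergic neuron genes, and presynaptic and neuropeptide genes. Markers of astrocytes, reactive astrocytes, microglia and macrophages, lymphocytes, the oligodendrocyte lineage, endothelial and mural cells, fibroblasts and matrix, ependyma and choroid plexus and erythroid cells were included for other cells such cultures can hold. The rest were complement, cytokine, NF-kB and Toll-like receptor, interferon-stimulated, antigen presentation, cell cycle, cholesterol synthesis, unfolded protein response, oxidative stress and apoptosis genes.

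The genes named in the text follow a rule. It takes up to 12 genes with the largest rise and 12 with the largest fall among those past the Benjamini-Hochberg threshold whose groups did not overlap. It adds all measured members of the neurotrophin list and, for each other list, up to 3 members past the threshold with the smallest p, or the 2 members with the smallest p where a list passed without such a member. The rule gave 58 genes. The groups, lists, tests, this rule and all alternatives except 2 were fixed before the data were examined. Genes named outside the rule are said to be so.

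Alternatives covered normexp background correction (offset 50), quantile normalization, median centring, no filter on dim probes and a filter on all 8 arrays. They also covered kept outlier spots, the authors' table, eBayes with trend and robust, slide as a fixed term or a random block, each slide that held both groups, the replicate number as a block, and each array left out in turn. Normexp used the median spot and local background signals, since the tables held no mean spot signal. Lists were also tested with an estimated correlation, with fry and with the mean of all probes of a gene. Array weights, and a fit without both arrays that stood apart, were added after the data had been seen. On simulated arrays with 50 probes changed at each size, among 24140 probes with the spread of this comparison, limma recovered 0% of changes of 0.5, 8% of changes of 1, 62% of changes of 2 and 88% of changes of 3 on the log2 scale, and called 4 unchanged probes. With slide as a fixed term it recovered 0%, 0%, 36% and 76%. A simulated shift of −0.5 of the 38 microglia and macrophage genes, among 12927 genes, was called by camera with 0 other lists called. The simulated probes were drawn independently, so this cannot show how often camera calls lists whose genes are correlated.

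The work used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.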

Results

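Cultures of embryonic rat hippocampal cells, which hold neurons and can hold glia and other cells of the dissected tissue, were compared after 72 h with NGF at 100 ng/ml or with vehicle. NGF is a neurotrophin that binds the receptor kinase TrkA (Ntrk1) and the receptor p75NTR (Ngfr). The comparison asks how the transcript levels of such cultures differ after NGF, and the title of the series puts inflammatory and immune genes at its centre. There were 4 cultures and 4 arrays per group. The array of vehicle 4 was the dimmest, and the arrays of vehicle 4 and NGF 2 stood apart from the rest. Their mean correlations with the other arrays, across probes, were 0.937 and 0.955, against 0.964 to 0.971 for the other arrays.

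NGF-treated cultures had lower signals for lists of microglia and macrophage genes and of inflammatory genes than vehicle cultures. Most members of each such list did not pass singly, and lymphocyte genes did not pass as a list. Microglia and macrophage genes shifted down as a group, as did Toll-like receptor and NF-kB genes, cytokines, complement and antigen presentation genes, and single beta-globin genes fell. Cell cycle, interferon-stimulated, reactive astrocyte and erythroid genes shifted down as well, but these calls were lost with an estimated correlation (adjusted p = 0.0892, 0.215, 0.0625 and 0.338). Cholesterol synthesis genes shifted up, and so did neuropeptide, oligodendrocyte lineage and neurotrophin system genes, whose calls were lost in the same way (adjusted p = 0.0892, 0.250 and 0.0892 with an estimated correlation). The 7 single genes that rose included Nefm and Cspg4. In limma's test 268 of 24159 probes changed, 251 lower and 17 higher, and 195 genes changed through their brightest probe, 188 lower and 7 higher. Of 27 gene lists, camera placed 9 lower and 4 higher, and with an estimated correlation 5 lower and 1 higher. Another split of the same 8 arrays gave 15 lists, and for 8 of the 13 lists, among them NF-kB, cytokine, antigen presentation and cell cycle genes, some other split gave a camera p as small.

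**Figure D1:**
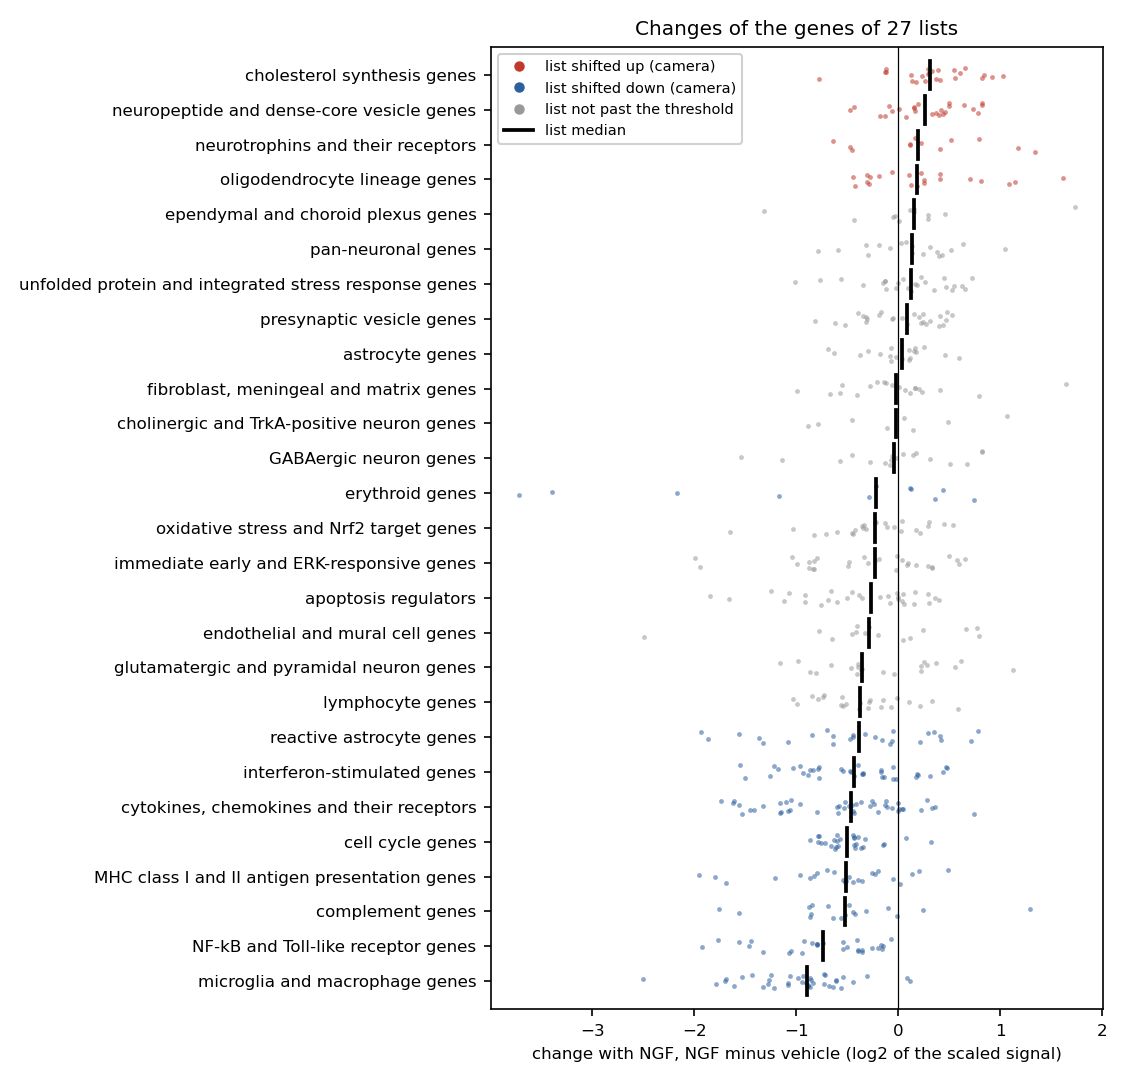
Changes of the measured genes of 27 lists (points, 1 per gene; x axis, log2 signal in NGF minus vehicle, means of 4 arrays per group) with the list median as a black bar; blue and red lists passed camera's test (down and up) and grey lists did not. The microglia and macrophage genes lie lowest, with a median of −0.90, and the cholesterol synthesis genes highest, with a median of 0.32.

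Microglia and macrophage genes, markers of the phagocytes of the brain and its borders, shifted down by a median of −0.90 (camera, adjusted p = 1.14e-19, or 0.0255 with an estimated correlation). Of 38 measured members 11 fell, 0 rose and 27 did not pass. Adjusted over the list alone, 31 fell. Lyz2, the lysozyme of phagocytes, fell from 5.34 ± 0.27 to 3.65 ± 0.22 (log2 scaled signal, SD, n = 4), a 3.23-fold lower signal (limma, adjusted p = 0.0109). Cd163, the scavenger receptor for haemoglobin-haptoglobin complexes, fell by 1.61 (SE 0.22, limma, adjusted p = 0.0177), and Ly86, the partner protein of Cd180, fell by 1.27 (SE 0.19, adjusted p = 0.0235). Only 1 of the 2 Ly86 probes passed. With normexp Cd163 changed by −1.01 and did not pass (adjusted p = 0.187). The list median was −0.89 with slide as a fixed term, −0.99 within slide 2 and −0.94 within slide 3.

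Among the 12 genes with the largest falls, several are known from myeloid cells. Lyve1, a hyaluronan receptor of lymphatic vessels and of some tissue macrophages, fell by 2.62 (SE 0.17, limma, adjusted p = 0.00137), a 6.15-fold lower signal. Gpr84, a receptor for medium-chain fatty acids on myeloid cells, was lower by 2 probes, with changes of −2.40 and −2.30. Msr1, the macrophage scavenger receptor, changed by −2.48 (SE 0.24) and Cd180, a Toll-like receptor homologue, by −2.36 (SE 0.42). Alox5, the enzyme that opens leukotriene synthesis, changed by −2.69 (SE 0.36), and S100a8, a calcium-binding protein of neutrophils and monocytes, by −2.77 (SE 0.39). Slc15a3, a lysosomal peptide and histidine transporter, changed by −2.43 (SE 0.38). Styxl2 changed by −2.70 (SE 0.43) and was well above background on 3 vehicle arrays and 1 NGF array. Alox5 and S100a8 were well above background on 2 of the 4 NGF arrays, and with normexp their changes were −1.21 and −1.23 and did not pass, nor did that of Styxl2 (−0.98). Cd180 changed by −1.43 with normexp and by −1.41 within slide 3.

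**Figure D2:**
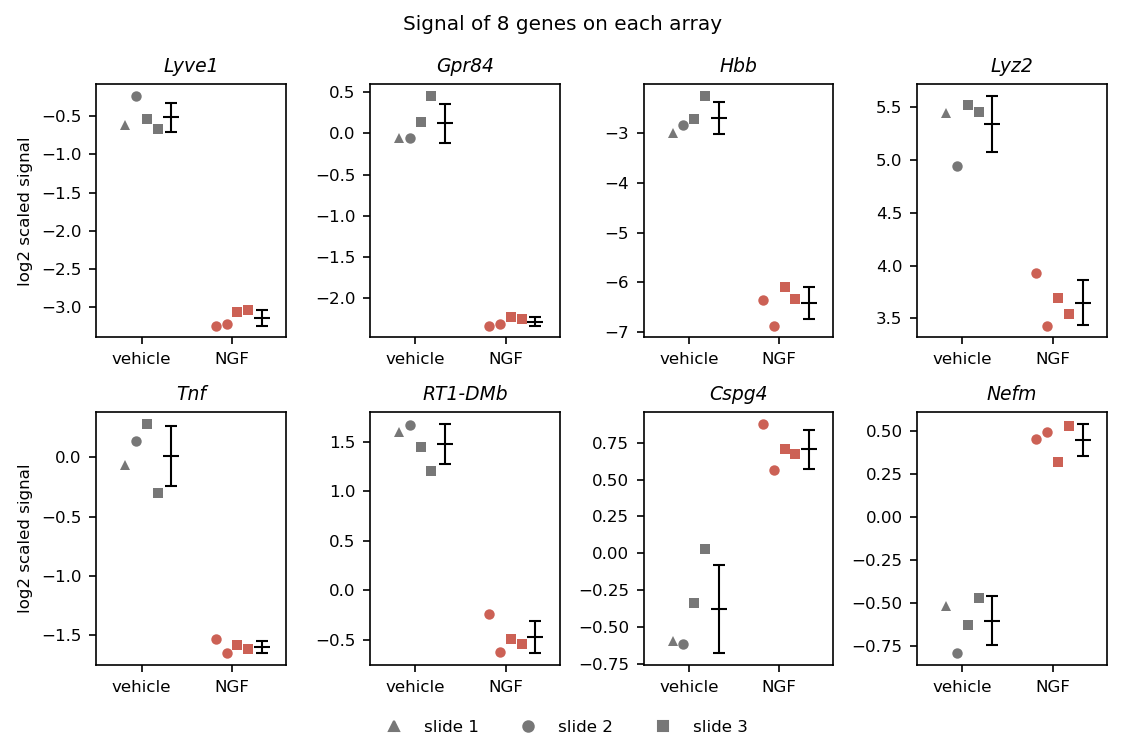
Signal of 8 genes on each array (y axes, log2 of the scaled signal, each with its own range; symbols mark the slide), with the mean and SD of the 4 arrays of each group as a bar. In each panel the NGF arrays lie wholly on 1 side of the vehicle arrays, as for Lyve1, at −3.24 to −3.04 with NGF and −0.67 to −0.24 with vehicle. All 8 genes were past limma's threshold, which makes such a separation likely beforehand.

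Lists of inflammatory signalling shifted down in the cultures in which the mean of the microglia and macrophage genes was lower (−0.07 to 0.36 on the NGF arrays, 1.12 to 1.23 on the vehicle arrays). NF-kB and Toll-like receptor genes shifted down by a median of −0.74 (camera, adjusted p = 4.11e-11, or 0.0377 with an estimated correlation). Before adjustment camera's p was 3.05e-12, where another split of the arrays gave 2.76e-13. Of 29 members 6 fell, 0 rose and 23 did not pass. Adjusted over the list alone, 14 fell. Nlrp3, the sensor of an inflammasome, fell by 1.92 (SE 0.21, limma, adjusted p = 0.00929), and its adaptor Pycard fell by 1.47 (SE 0.22, adjusted p = 0.0212). Irak3, a brake on Toll-like receptor signalling, also fell by 1.05 (SE 0.16), with 1 of its 2 probes past the test. The NF-kB list shares 1 fallen member, Cd14, with the microglia list. With normexp Nlrp3 changed by −1.20 and did not pass (adjusted p = 0.0598). This list's median was −0.66 with slide as a term and −0.94 and −0.57 within slides 2 and 3. Cytokines, chemokines and their receptors shifted by a median of −0.46 (camera, adjusted p = 9.88e-07, or 0.0255 with an estimated correlation). Of 46 members 6 fell, 0 rose and 40 did not pass, with 11 fallen when adjusted over the list alone. Tnf fell by 1.61 (SE 0.18, limma, adjusted p = 0.00929), and Il1a fell by 1.62 (SE 0.16, adjusted p = 0.00658). Tgfb1, whose product is known to dampen inflammation, also fell by 1.73 (SE 0.24, limma, adjusted p = 0.0181). For the cytokine list the medians were −0.56 with slide as a term and −0.47 and −0.70 within the slides.

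Complement and antigen presentation genes followed the same direction. The complement list had a median of −0.52 (camera, adjusted p = 0.00115, or 0.0377 with an estimated correlation). Of 19 members 2 fell, 0 rose and 17 did not pass. Adjusted over the list alone, 6 fell and 1 rose. The receptor gene C3ar1 fell by 1.56 (SE 0.18, limma, adjusted p = 0.00979), and Cfb, factor B of the alternative pathway, fell by 1.76 (SE 0.26, adjusted p = 0.0225; −1.09 within slide 2). The list includes 3 members of the microglia list, 0 of which fell by the test over all probes. Its median was −0.60 with slide as a term, −0.41 within slide 2 and −0.56 within slide 3, where camera's call was lost (adjusted p = 0.0615). Genes of MHC class I and II antigen presentation shifted by −0.51 (camera, adjusted p = 1.04e-04, or 0.0255 with an estimated correlation). Of 25 members 3 fell, 0 rose and 22 did not pass, and 4 fell when adjusted over the list alone. The 3 were the class II genes RT1-DMb, which fell by 1.95 (SE 0.18, limma, adjusted p = 0.00590), and RT1-DMa, which fell by 0.96 (SE 0.15), both needed for loading peptides onto class II molecules, and Cd74, the invariant chain, which fell by 1.69 (SE 0.19). Slide as a term gave a median of −0.47, and slides 2 and 3 gave −0.41 and −0.60.

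Interferon-stimulated genes had a median of −0.43 (camera, adjusted p = 7.43e-04; adjusted p = 0.215 with an estimated correlation). Only Stat2, a transducer of interferon signals, passed limma's test, with a fall by 0.96 (SE 0.17, adjusted p = 0.0393), among 37 members, and with normexp it did not (−0.88, adjusted p = 0.0526), while 9 fell when adjusted over the list alone. The median was −0.41 with slide as a term, −0.42 within slide 2 and −0.46 within slide 3. Reactive astrocyte genes had a median of −0.38 (camera, adjusted p = 0.00754; adjusted p = 0.0625 with an estimated correlation), with 4 of 26 fallen, 0 risen and 22 not past the test, and 7 fallen when adjusted over the list alone. Among them Steap4, a metalloreductase, fell by 1.93 (SE 0.20, limma, adjusted p = 0.00739). Lcn2, which binds siderophores, fell by 1.37 (SE 0.21) and Cp, a copper ferroxidase, fell by 1.08 (SE 0.16). Only 1 of the 2 Cp probes passed. The reactive astrocyte list shares 1 fallen member, Cd14, with the microglia list. For this list slide as a term gave −0.38, slide 2 gave −0.50, and slide 3 gave −0.24 without a call (camera, adjusted p = 0.141). General astrocyte genes did not pass, with a median of 0.04, a mean of −0.01 and 0 of 19 members past the test over all probes or over the list alone (camera, direction up, adjusted p = 0.339), though camera called them up with normexp (adjusted p = 0.0368).

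Beta-globin genes, which encode subunits of haemoglobin, had the largest falls of the genes named by size. Hbb fell by 3.72 (SE 0.24, limma, adjusted p = 0.00137), a 13.2-fold lower signal, and Hbb-bs fell by 3.13 (SE 0.35, adjusted p = 0.00929). Both were well above background on all vehicle arrays, but on only 3 (Hbb) and 2 (Hbb-bs) of the 4 NGF arrays. Hbe2 fell by 3.39 (SE 0.28, limma, adjusted p = 0.00520), a 10.5-fold lower signal. It was well above background on 4 vehicle arrays and 0 NGF arrays, so this fold depends on the background correction. Hbb-b1 fell by 2.17 (SE 0.25) by its brightest probe, and its other probe passed in the same direction. These genes belong to the same family and the probe sequences were not compared, so which of them the probes read is uncertain. The erythroid list that holds 3 of them shifted down by camera with a median of −0.21 (adjusted p = 0.0318; adjusted p = 0.338 with an estimated correlation). Of its 11 members 3 fell, 0 rose and 8 did not pass, and 4 fell and 1 rose when adjusted over the list alone. Its median was −0.26 with slide as a term, −0.26 within slide 2 (camera, adjusted p = 0.0537) and −0.42 within slide 3. The call was lost without vehicle 2, vehicle 4, NGF 1 or NGF 3 (adjusted p = 0.0700, 0.0766, 0.0522 and 0.0639), and the median was 0.01 without vehicle 4 and 0.13 without NGF 4. That call was also lost with quantile normalization (median −0.04, adjusted p = 0.0595) and among probes above background on all arrays (median −0.08, adjusted p = 0.467). With normexp Hbb changed by −2.01 and passed (adjusted p = 0.00999), while Hbb-bs and Hbe2 changed by −1.46 and −1.32 and no longer passed.

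Cell cycle genes shifted down by a median of −0.50 (camera, adjusted p = 5.22e-07; adjusted p = 0.0892 with an estimated correlation), although 0 of 28 members passed limma's test. Adjusted over the list alone, 10 fell. The members with the smallest p were Kif20a, a kinesin of cytokinesis, at −0.78 (SE 0.18, limma, adjusted p = 0.106), and Ttk, a spindle checkpoint kinase, at −0.78 (SE 0.20, adjusted p = 0.154). Medians were −0.49 with slide as a term, −0.68 within slide 2 and −0.40 within slide 3, where camera gave an adjusted p of 0.0515. Cholesterol synthesis genes shifted up by a median of 0.32 (camera, adjusted p = 1.04e-04, or 0.0255 with an estimated correlation). Of 24 members 0 passed limma's test and 2 were higher when adjusted over the list alone. Idi1 and Hmgcs1, enzymes of the mevalonate pathway, had changes of 1.03 (SE 0.22, limma, adjusted p = 0.0803) and 0.92 (SE 0.23, adjusted p = 0.122; 0.57 within slide 3). The cholesterol list's median was 0.24 with slide as a term, 0.32 within slide 2 and 0.15 within slide 3.

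**Figure D3:**
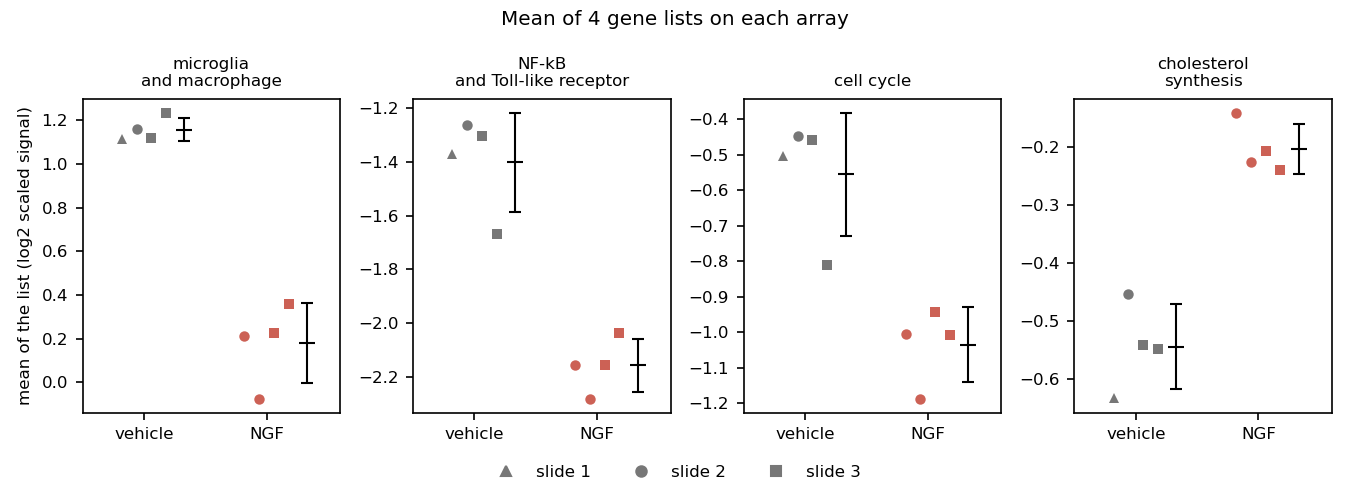
Mean of the measured genes of 4 lists on each array (y axes, log2 of the scaled signal, each with its own range; symbols mark the slide), with the mean and SD of the 4 arrays of each group as a bar. The microglia and macrophage mean was 1.16 ± 0.05 (SD) with vehicle and 0.18 ± 0.18 with NGF, and the cholesterol synthesis mean was −0.54 ± 0.07 and −0.20 ± 0.04.

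Neuropeptide and dense-core vesicle genes shifted up by a median of 0.26 (camera, adjusted p = 2.39e-04; adjusted p = 0.0892 with an estimated correlation), with 0 of 26 past limma's test and 2 higher when adjusted over the list alone. Vip had a change of 0.82 (SE 0.18, limma, adjusted p = 0.0919) and Crh, the corticotropin-releasing hormone gene, one of 0.78 (SE 0.18, adjusted p = 0.0977), while 1 of the 2 Crh probes passed. The Crh value was 0.07 with normexp (adjusted p = 0.900) and passed without vehicle 4 (0.85, adjusted p = 0.0427). Slide as a term gave a median of 0.26, slide 2 gave 0.39 and slide 3 gave 0.10. With normexp the median was −0.06, though camera kept its direction. Oligodendrocyte lineage genes shifted up by a median of 0.19 (camera, adjusted p = 0.00542; adjusted p = 0.250 with an estimated correlation), and fry gave an adjusted p of 0.171. Of 21 members, Cspg4, a proteoglycan of oligodendrocyte precursors and pericytes, rose by 1.09 (SE 0.20, limma, adjusted p = 0.0451), and 20 did not pass, with 3 higher when adjusted over the list alone. The medians were 0.17 with slide as a term, 0.20 within slide 2 and 0.28 within slide 3.

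The neurotrophin system itself shifted up as a group of 12 genes, by a median of 0.19 (camera, adjusted p = 0.0159; adjusted p = 0.0892 with an estimated correlation). No member passed limma's test over all probes (0 rose, 0 fell), and 2 were higher when adjusted over the list alone. Bdnf and Ntf3, which encode neurotrophins, had changes of 1.34 (SE 0.35, limma, adjusted p = 0.148) and 1.17 (SE 0.45, adjusted p = 0.303), and Ngf and Ntf4 had −0.45 and −0.47. With normexp Bdnf and Ntf3 had 0.17 and 0.40, and without vehicle 4 Bdnf passed (0.98, adjusted p = 0.0263) while Ntf3 had 0.69. The receptor genes Ntrk1, Ntrk2 and Ntrk3 differed by 0.11 (SE 0.29), 0.12 (SE 0.36) and 0.22 (SE 0.24), less than the spread between cultures. Ngfr had a change of 0.41 (SE 0.16, limma, adjusted p = 0.323). Ntrk1 and Ngfr were dim, with vehicle means of −5.97 and −6.27, so their values cannot show a lack of change. Ntrk1, Ngfr and Ntf3 were well above background on 3 vehicle arrays and Ntf4 on 2, and each of them on 4 NGF arrays. Among the sortilin family Sorcs3 had 0.80 (SE 0.17, adjusted p = 0.0833; 0.51 with normexp), Sorcs2 had 0.52, Sort1 had 0.17 and Sorcs1 had −0.64. The list median was 0.28 with slide as a term (camera, adjusted p = 0.0178), and 0.35 and 0.27 within slides 2 and 3, where the call was lost (adjusted p = 0.146 and 0.0523). It was also lost without vehicle 3 (median 0.14, adjusted p = 0.0629), with normexp, with quantile normalization and among probes above background on all arrays (adjusted p = 0.0562, 0.0563 and 0.0627) and with the mean of all probes per gene, where the median was −0.00 (adjusted p = 0.105). Without vehicle 4 the list median was 0.36 (camera, adjusted p = 0.00323).

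The 7 genes that rose belong to several groups. Nefm, the medium neurofilament subunit, rose by 1.05 (SE 0.16, limma, adjusted p = 0.0235), from −0.60 ± 0.14 to 0.45 ± 0.09 (SD). Grp, the gastrin-releasing peptide gene, rose by 1.22 (SE 0.22) and Adarb1, which encodes an RNA-editing adenosine deaminase, by 0.89 (SE 0.16). Ogn, a small matrix proteoglycan, rose by 1.65 (SE 0.27), Chia, a chitinase, by 1.49 (SE 0.17), and Brinp3 by 1.16 (SE 0.20). Ogn, Chia and Brinp3 were well above background on 2, 3 and 3 of the vehicle arrays. With normexp 2 of the 7 (Nefm and Cspg4) passed limma's test, and Ogn, Chia, Brinp3, Grp and Adarb1 had 0.22, 0.27, 0.04, 0.68 and 0.84. Nefm and Cspg4 each lost the call in 7 of the 8 fits without 1 array, and also with slide as a fixed term. Ogn, Brinp3, Grp and Adarb1 likewise lost it in 7 of these fits, and Chia in 3. Within slide 3 Grp had 0.79.

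The remaining neuronal lists did not pass camera's test in the reported fit. Pan-neuronal genes had a median of 0.14 (adjusted p = 0.0507), with Nefm as the only riser among 18 over all probes and over the list alone. Without vehicle 4 this list passed (median 0.25, camera, adjusted p = 0.0101). Presynaptic vesicle genes had a median of 0.08 (adjusted p = 0.0888), with 0 of 27 past the test by either adjustment. Their list also passed without vehicle 4 (median 0.23, camera, adjusted p = 0.00645). Both lists passed without both arrays that stood apart, a fit chosen after the data had been seen (adjusted p = 0.00102 and 1.35e-04). Glutamatergic genes stood at −0.36 (adjusted p = 0.935), with 0 of 21 past the test and 1 lower when adjusted over the list alone. Without vehicle 4 their median was −0.05. GABAergic genes stood at −0.04 with a mean of −0.05, against camera's direction, which was up (adjusted p = 0.436), with 0 of 18 past the test and 1 higher over the list alone. Cholinergic genes likewise had a median of −0.02 and a mean of −0.06 where camera's direction was up (adjusted p = 0.577), with 0 of 8 past the test and 1 higher over the list alone. Immediate early and ERK-responsive genes had a median of −0.23 (adjusted p = 0.470), with 3 of 29 lower over the list alone. Plaur, the urokinase receptor gene, was the only member past limma's test over all probes and fell by 1.99 (SE 0.25, adjusted p = 0.0125). Only 1 of the 2 Plaur probes passed.

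Other cell types and stress programmes did not pass camera's test in the reported fit either. Endothelial and mural genes had a median of −0.29 (adjusted p = 0.849), and of 15 members Esam, an endothelial adhesion molecule, fell by 2.50 (SE 0.34, limma, adjusted p = 0.0171), alone also over the list. Fibroblast and matrix genes had a median of −0.02 and a mean of −0.01 where camera's direction was up (adjusted p = 0.577), with Ogn the riser among 20 and 2 higher over the list alone. Ependymal and choroid plexus genes had a median of 0.16 (adjusted p = 0.0888), with 0 of 13 past the test and 1 higher and 1 lower over the list alone. Without vehicle 4 this list passed (median 0.26, camera, adjusted p = 0.0109). Its median was 0.39 within slide 2 and −0.12 within slide 3. Lymphocyte genes had a median of −0.37 (adjusted p = 0.139), with 0 of 23 past the test by either adjustment. Apoptosis regulators had a median of −0.26 (adjusted p = 0.0918), and Bik, a pro-apoptotic member of the Bcl-2 family, fell by 1.66 (SE 0.27, limma, adjusted p = 0.0317) as the only one of 30 by either adjustment, though not with normexp (−1.09). Oxidative stress genes had a median of −0.22 (adjusted p = 0.208), with 0 of 25 past the test and 1 lower over the list alone. The apoptosis and oxidative stress lists were, however, both called lower by fry (adjusted p = 0.00253 for each). Both passed camera's test without both arrays that stood apart, a fit chosen after the data had been seen (adjusted p = 0.0363 and 0.0385). Neither passed it with slide as a fixed term (adjusted p = 0.192 and 0.383) or with normexp (adjusted p = 0.274 and 0.776). Unfolded protein and integrated stress response genes had a median of 0.12 (adjusted p = 0.0676), with 0 of 25 past the test and 1 higher and 1 lower over the list alone. With slide as a fixed term the pan-neuronal, presynaptic, lymphocyte and unfolded protein lists passed camera's test (adjusted p = 0.0249, 0.0398, 0.0421 and 0.0244), as they did with normexp (adjusted p = 0.00375, 0.0190, 0.0235 and 0.00335).

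The median change of all measured genes was −0.06. Relative to it the list medians were −0.84 for microglia and macrophage genes, −0.68 for NF-kB and Toll-like receptor genes and −0.46 for complement. They were −0.45 for antigen presentation and for cell cycle genes, −0.41 for cytokines, −0.37 for interferon-stimulated and −0.32 for reactive astrocyte genes, and −0.16 for erythroid genes. The higher lists stood at 0.37 (cholesterol synthesis), 0.32 (neuropeptides), 0.25 (neurotrophins) and 0.25 (oligodendrocyte lineage). Over all kept probes the median was −0.10, and −0.29, 0.05 and 0.09 with normexp, quantile normalization and median centring.

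All 195 changed genes had NGF arrays wholly on 1 side of the vehicle arrays, as did 1807 (14.0%) of all measured genes, where chance alone gives 2.86%. For the 195 this follows closely from the call itself and adds no support. With the Westfall-Young correction named by the study, 6 probes passed, all at the smallest p that the permutations can give (0.0286). These were Hbb, Hbe2, Lyve1, both Gpr84 probes and a probe without a gene name that was higher, which like Cd14 above was singled out after its values were seen. With slide as a fixed term limma called 3 probes (1747 at an unadjusted p under 0.05), which were Hbb (−3.75, adjusted p = 0.0330), Hbe2 (−3.62, adjusted p = 0.0448) and the same unnamed probe (3.59), and within slides 2 and 3 alone it called 0 and 0 (408 and 1453 unadjusted). With the slide term the changes of the 40 named genes past the threshold were 0.874 to 1.101 times those without it, while their SEs were 0.985 to 1.41 times as large, with a median of 1.27 (Lyve1 −2.66, SE 0.23). Without vehicle 1, 2, 3 or 4 the count of changed probes was 44, 47, 60 or 549, and without NGF 1, 2, 3 or 4 it was 80, 127, 67 or 43. The Westfall-Young count was 6, 4, 3 or 8 and 2, 6, 5 or 4 in the same order. Of the 40 named genes past the threshold, 11 passed in all 8 of these fits, namely Hbb, Hbb-b1, Hbb-bs, Hbe2, Lyve1, Gpr84, Msr1, Nlrp3, Il1a, RT1-DMb and Steap4, and the 7 that rose passed in 1 to 5 of them. Without both arrays that stood apart 537 probes changed and 18 lists shifted, and with array weights 1471 probes and 16 lists, both fits chosen after the data had been seen. Of the named genes that did not pass, Bdnf, Crh, Hmgcs1, Idi1, Kif20a, Sorcs2, Sorcs3, Ttk and Vip did so with array weights, Bdnf, Hmgcs1 and Idi1 without both arrays, and Idi1 with trend and robust (adjusted p = 0.0467).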

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

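The tests of explanations in this part, the marker sets for macrophages and microglia and the comparisons of erythroid genes were chosen after the results they measure had been seen, so they can exclude an explanation but cannot establish one. The alternative fits they draw on were planned.

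The fall of the microglia and macrophage genes, whose median change was −0.90, was weighed against 3 explanations, and a difference between slides is excluded as its whole cause, since the highest of the list medians with slide as a fixed term and within slides 2 and 3 was −0.8947. A lower share of these cells, with all their markers lowered alike, is undecided, because 6 of the 38 members still differed after each array was centred on the list mean (Cybb −0.81, Lyz2 −0.71 and Cd163 −0.63 below it, Sall1 0.67, Olfml3 1.07 and Hexb 1.09 above it) and expression in other cells could spread the changes too. A fall mainly of border-associated macrophages remains possible, as the change of their markers, picked after some values were seen, minus that of homeostatic microglia markers was −0.5719 (exact permutation p = 0.0286, the smallest that 4 against 4 arrays can give; −0.98 within slide 2 and −0.39 within slide 3). Of 9 such markers only Lyve1, Cd163 and Siglec1 passed, while Mrc1 (−2.51), Folr2 (−1.01), Clec10a (−0.87), Cd36 (−0.53), Pf4 (−0.39) and F13a1 (0.17) did not. The 10 homeostatic markers were lower too, by a mean change of −0.66 (exact permutation p = 0.0286). Of these P2ry13 passed (−1.53), while Slc2a5 (−1.27), Cx3cr1 (−1.27), Tmem119 (−1.245), P2ry12 (−0.54), Gpr34 (−0.44), Sall1 (−0.305), Sparc (−0.20), Olfml3 (0.09) and Hexb (0.11) did not. The gap between the 2 sets therefore depends on the markers taken. An effect of NGF on gene expression within these cells remains a hypothesis that these arrays cannot separate from a loss of cells.

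The fall of the beta-globin genes was weighed against 2 explanations, and neither could be decided. The first was taken as fewer red blood cells or precursors with all erythroid genes lowered alike, and a loss that lowers them unevenly was not tested. The mean change of the 7 measured erythroid genes outside the beta-globin family stood 2.348 above that of the 5 measured genes of the family, fallen or not (2.17 and 2.54 within slides 2 and 3). That gap does not settle it, because several of the 7 are dim or may be read from other cells, and the brightest, the alpha-globin gene Hba-a1, was lower too without passing (−1.16, SE 0.32, limma, adjusted p = 0.166), while Ahsp was at 0.75. Whether 1 transcript was read by probes of several beta-globin genes is open, since 4 measured genes of the family were lower and Hbg1 was not (0.45), and the probe sequences were not used here. An effect of NGF on globin expression was not tested apart from these.

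Of the changed probes 93.7% were lower. Each other scaling called its own set of probes, 190 with quantile normalization, 98 with median centring and 226 with normexp. At least 84.74% of each set were lower, so a majority of lower probes among those called did not depend on which of these scalings was used. Without the dimmest array, vehicle 4, 549 probes were called and 84.52% of them were lower, so it did not depend on that array either. The share among the same 268 probes was not computed. Among probes at an unadjusted p under 0.05 the majority does depend on the scaling, with 1008 higher and 2337 lower in the reported fit, 1834 and 1608 with quantile normalization, and 1946 and 1453 (42.75% lower) with median centring. A response to NGF that lowers more transcripts than it raises therefore remains a hypothesis for the changed probes alone, and a change in the mix of cells remains open too.

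The 8 arrays can be split into 4 and 4 in 35 ways. For the number of changed probes by Benjamini-Hochberg, a chance arrangement of the arrays is unlikely but not excluded. Only 1 of 35 splits, the real one, gave a count as large as 268, and the highest other count was 3. That is the smallest share that 35 splits can give. This result holds for the fit without slide, whose splits exchange arrays across slides, and with slide as a fixed term the real count was 3. For the Westfall-Young count the splits decide nothing, since with 35 relabellings at most 1 split can hold a probe under 0.05, so that once the real split gave 6 the highest other count had to be 0 (1 of 35). For the number of lists a chance arrangement stays open, because 2 of 35 splits gave 13 or more. The highest other count was 15, from vehicle 4 with NGF 1, 3 and 4 against the rest. Taken singly, camera's unadjusted p was as small in some other split for 8 of the 13 lists, counting the real split in 4 of 35 for interferon-stimulated genes, 3 of 35 for cell cycle and for oligodendrocyte lineage genes, and 2 of 35 for NF-kB, cytokine, antigen presentation, reactive astrocyte and neurotrophin genes. Only the real split gave a p as small for microglia, complement, erythroid, cholesterol and neuropeptide genes, although another split gave 2.27e-19 for the microglia list against 4.24e-21.

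Single arrays stood out in 11 of 174 groups of 4 arrays (6.32%), where chance alone marks about 1 in 20 (5%). Each was marked because the gap between an extreme array and its nearest neighbour, divided by the group's range, passed the critical value of Dixon's test. Of the 11, 6 concern vehicle 4 and 2 concern NGF 2. Vehicle 4 lay apart for Ntf3 (gap ratio 0.830; −5.54, others −3.78 to −3.42), Ntrk2 (0.865; 2.67, others at most 1.31), Sorcs1 (0.867; 0.30, others −0.95 to −0.79) and S100a8 (0.899; −3.09, others −4.70 to −4.53). It also lay apart for the mean of the cell cycle genes (0.851; −0.81, others −0.50 to −0.45) and that of the unfolded protein response genes (0.870; 0.56, others 0.85 to 0.89). NGF 2 lay apart for Hmgcs1 (0.844, with 4.62 against 3.80 to 3.93) and for Nlrp3 (0.830, with −6.21 against −5.64 to −5.53). Vehicle 2 lay apart for Lyz2 (0.866, with 4.94 against 5.44 to 5.52), and NGF 4 for Ntf4 (0.921, with −8.13 against −6.75 to −6.63). NGF 3 lay apart in the percentage of probes well above background (0.893, with 76.5 against 81.1 to 81.6).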

How the results depend on the processing

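Array weights, and the fit without both arrays that stood apart, were chosen after the data had been seen. None of the 40 called named genes turned its direction, and camera kept its direction for each called list. The medians of 3 such lists turned, of erythroid genes without vehicle 4 (0.0097) and NGF 4 (0.13, still called down), of neuropeptide genes with normexp (−0.0620, still called up) and of neurotrophin genes with the mean of all probes (−0.0021). The 40 called named genes kept their side of the threshold in 378 results and lost it in 213 over the other settings, and 156 and 164 when 1 replicate was left out. The 13 called lists kept it in 213 and lost it in 21, and 99 and 5 without 1 replicate. Uncalled lists gained a call in 29 and 10 results, and uncalled genes in 13 and 2. The lists of microglia, cytokine, NF-kB, antigen presentation and cholesterol genes passed throughout.

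Against 268 changed probes, the count was 98 with median centring, 178 with no filter, 3 with slide as a fixed term, 0 within slide 2, 0 within slide 3 and 0 with the replicate number as a block (2195 at an unadjusted p under 0.05 by limma). It was 1471 with array weights, 537 without both arrays that stood apart, 3345 unadjusted, and 43 to 549 without 1 replicate. Whether the replicate numbers pair the cultures is not known. The deviations of arrays of the same number, not their signals, had correlations of −0.24, 0.17, −0.17 and −0.41. Those of arrays with different numbers ran from −0.33 to 0.52, and so few pairs cannot settle it. Against 6 probes by Westfall-Young, the count was 1 with quantile normalization, 13 among probes above background on all arrays, 2 to 8 without 1 replicate, and 0 without both arrays, where 10 relabellings allow no p under 0.1. Fewer arrays lower the power within slides. Otherwise the cause was not tested. With an estimated correlation 6 lists passed.

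Values of uncalled results that turned were, with normexp, Ngfr −0.38, Ntrk1 −0.41, cholinergic genes −0.49, glutamatergic −0.38 and fibroblast −0.39. With slide as a fixed term they were Ntrk1 −0.11, Ntrk2 −0.0110 and glutamatergic −0.33. Within slide 2 they were Sort1 −0.56, immediate early genes −0.0671, endothelial 0.0626 and fibroblast −0.31, and within slide 3 Ntrk1 −0.41, Ntrk2 −0.49 and glutamatergic −0.15. With array weights Sort1 was −0.0628 and glutamatergic −0.13, and without both arrays glutamatergic was 0.11 and endothelial −0.0370. Glutamatergic genes had −0.36 with no filter, −0.15 with the filter on all arrays and −0.36 with trend and robust, and fibroblast genes −0.13 with that filter. For several of these lists it was camera's direction that turned, not the median. Without 1 replicate Ntrk1 ran from −0.0466 to 0.29, Ntrk2 from −0.0311 to 0.49, Sort1 from −0.21 to 0.42, glutamatergic genes from −0.43 to −0.0516 and endothelial genes from −0.37 to −0.0296. Signal over background limits what the dim probes show, and with normexp 26 of the 40 called genes still passed. With median centring, which leaves the background as it was, 25 of the 40 passed.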

Other observations

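The genes in this part were chosen after their values were seen, and no list of them was tested. Of the 195 changed genes, 155 belong to none of the 27 lists, 151 of them lower and 4 higher. Among the lower ones are the kinase genes Lyn (−2.03), Fgr (−1.77), Btk (−1.69), Fes (−1.60) and Hck (−1.22) and the phosphatase gene Ptpn6 (−1.42, limma). Siglec1, a sialic acid receptor of macrophages, fell by 1.72, and Adgre5, an adhesion receptor of leukocytes, fell by 2.20. Colec12, a scavenger receptor, fell by 2.22, and Csf3r, the receptor for granulocyte colony-stimulating factor, fell by 1.63. The enzyme genes Acod1, Kmo, Gch1 and Ch25h changed by −2.04, −1.88, −1.60 and −1.54. Stat6, a transducer of interleukin-4 signals, fell by 2.12, and Sting1, an adaptor for cytosolic DNA sensing, fell by 1.38.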
